A study of Homo sapiens with 6 samples.

How the data were processed

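Total RNA of 6 samples of cells labelled SKOV3 was used, per the labels' protocols with Trizol and an Illumina TruSeq RNA kit. The submitters' processing notes name Trimmomatic, HISAT2, Cufflinks and HTSeq and the build GRCh38, without versions, roles or order. The deposited values are FPKM per gene symbol, per the file headers, with 1 value per symbol and library and no pooled replicates. Strand, filters and gene annotation are not given in the sources used here. FPKM hides the number of fragments, so the depth is unknown and no counting intervals are given. Since only FPKM was used, the planned count tests were replaced by a test for normalized values, named beforehand for that case. Fragments shared by near-identical genes may be split among copies by the authors' software, and 12 symbols had turned into dates and cannot be read as genes. Mitochondrially encoded genes are not analysed here.

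The groups follow the labels, with 3 vehicle and 3 rhCCL20 libraries. Genes with at least 1 FPKM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3, with eBayes and a trend, on log2(FPKM + 1), with group as the only term. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and a fold of 2 was applied as a further criterion. An exact test of 3 libraries against 3 cannot give a p below 0.1. Intervals are 95% intervals of limma. Gene lists for an ovarian carcinoma line and a chemokine, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, where at least 3 members were tested. 2 lists had fewer, those of CCL20 with its receptor and of mitochondrially encoded proteins. List symbols were matched as given or through synonyms of a RefSeq gene table, in which 19630 of the 20030 symbols were found.

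The rule for named genes, fixed at the same time, takes CCL20 and CCR6, up to 10 genes in each direction among those past the threshold with groups that do not overlap and a mean of at least 1 FPKM in a group, of each list up to 4 members past the threshold or else the 1 with the smallest p, and the 5 genes with the smallest adjusted p. Genes outside the rule serve as examples, or are named as chosen after their values were seen. ERBB2, CDKN2A, CDH1, EPCAM, KRT8 and VIM are members of the fixed lists whose levels were singled out after they were seen. Gene positions are from GENCODE on GRCh38, which may differ from the authors' annotation.

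The procedure was tested on simulated data, 20 sets of 10263 genes with 200 changed. Of the calls 4.80% were false, and 1 of 20 sets without a change gave a call. Noise was drawn independently for each gene and library. These rates therefore do not cover correlation between genes or effects of single libraries. Alternatives were other pseudocounts, filters, normalizations and eBayes settings, the replicate number as a block, and leaving out each library. Summing the GAGE genes, and removing a trend on transcript length and GC content, were added after seeing the data.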

Results

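RNA was sequenced from 6 samples of human cells labelled SKOV3, the name of an ovarian carcinoma line. Of these, 3 were of cells exposed for 24 h to vehicle (5% trehalose) and 3 of cells exposed to recombinant human CCL20 (rhCCL20) in the same vehicle. CCL20 is a chemokine that binds the receptor CCR6. Each library has an FPKM value (fragments scaled by transcript length and by the mapped fragments of the library) for each of 20030 gene symbols, of which 16355 were above 0 in at least 1 library. The summed FPKM lay between 301805 and 310080, and between 10191 and 10238 genes reached 1 FPKM in a library. The absolute depth is unknown. From the spacing of low values, depth relative to vehicle replicate 1 lay between 0.948 and 1.09. It was 0.948 and 0.981 in vehicle replicates 2 and 3 and 1.01, 1.06 and 1.09 in rhCCL20 replicates 1 to 3. Relative depth thus went with the group, which limits the reading of genes near 0. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

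The cells expressed keratins and vimentin together. The keratin KRT8 averaged 659 ± 18 FPKM in vehicle (SD, n = 3) and 623 ± 16 FPKM with rhCCL20 (SD, n = 3), and the mesenchymal filament gene VIM averaged 341 ± 2.9 and 339 ± 14 FPKM. The epithelial adhesion genes CDH1 and EPCAM averaged 0.175 and 0.017 FPKM over the 6 libraries. SKOV3 is known as a line with amplified ERBB2 and deleted CDKN2A. In these libraries ERBB2, a receptor tyrosine kinase, averaged 7.83 FPKM, with a range of 7.23 to 9.20 over the 6 libraries, and stood at percentile 47.1 of the tested genes. CDKN2A, a cell cycle inhibitor, averaged 16.4 FPKM with a range of 15.3 to 17.4. The line is therefore called by its label only, and every comparison below concerns cells with these levels.

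The comparison of rhCCL20 with vehicle asked how exposure to the chemokine alters the transcriptome of the line. GAGE12G, a member of the GAGE family of cancer/testis antigens, was the only gene that passed the test. It fell from 6.09 ± 0.90 FPKM in vehicle (SD, n = 3) to 2.41 ± 0.24 FPKM with rhCCL20 (SD, n = 3), and all 3 treated libraries lay below all 3 vehicle libraries. No gene rose, and genes of inflammation, adhesion, invasion, proliferation and metabolism did not pass. Of 10263 genes tested with limma and Benjamini-Hochberg adjustment, 1 fell and 0 rose, and 485 genes (4.73%) had an unadjusted p under 0.05, 264 of them higher and 221 lower with rhCCL20. The log2 fold change of GAGE12G was -1.05 (SE 0.093, 95% interval -1.26 to -0.84, limma adjusted p = 0.00713) on the scale of log2(FPKM + 1), which understates changes of low genes. With no filter on low values, 16355 genes were tested and 0 passed, with 861 at an unadjusted p under 0.05 and an adjusted p of 0.458 for GAGE12G in limma. Without vehicle replicate 1, 3 genes passed, with LYZ and S100A9 higher beside the lower GAGE12G.

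GAGE12G lies on chromosome X from 49570434 to 49577754 on the plus strand in GENCODE annotation of GRCh38, where it is a protein-coding gene in a cluster of near-identical copies. Its value is uncertain for that reason, since near-identical copies can share reads. GAGE12H, the most abundant copy, averaged 38.7 ± 2.3 FPKM in vehicle and 34.7 ± 1.7 FPKM with rhCCL20 (SD, n = 3 each), a log2 fold change of -0.15 with a limma adjusted p of 0.937. Summed over the 12 GAGE genes listed, the family averaged 49.9 ± 1.5 FPKM in vehicle and 42.0 ± 2.5 FPKM with rhCCL20 (SD, n = 3 each). The log2 fold change of the sum was -0.24 (95% interval -0.35 to -0.14, limma adjusted p = 0.695), so with the copies summed 0 genes passed, and 483 had an unadjusted p under 0.05. This sum was added after the values were seen.

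**Figure D1:**
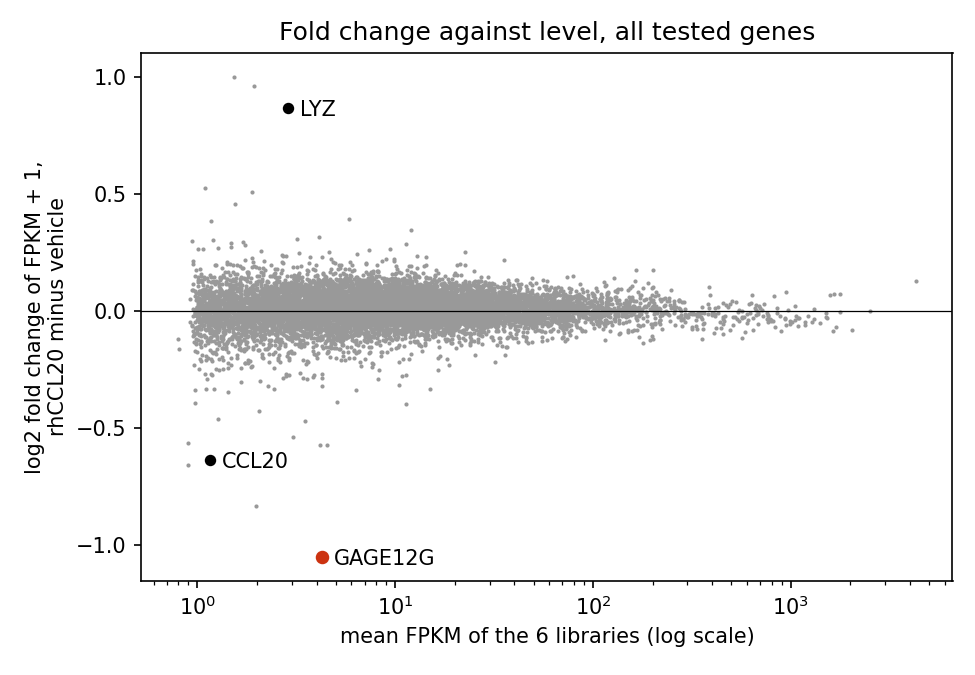
Each point is 1 of the 10263 tested genes, with mean FPKM over the 6 libraries on a log axis and the log2 fold change of FPKM + 1 (rhCCL20 minus vehicle) on the vertical axis. GAGE12G, at -1.05, is the only gene past the threshold in limma, and CCL20 and LYZ are marked for orientation.

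Most genes were held within narrow limits on the scale of log2(FPKM + 1), which understates changes of low genes. The 95% interval of the fold change of FPKM + 1 lay within 1.5-fold in either direction for 10219 genes (99.6%). It lay within 2-fold for 10248 genes (99.9%). Of 6816 tested genes with a mean of at least 5 FPKM, it lay within 1.5-fold for 6808 (99.9%). The median SE of the log2 fold change was 0.057. The groups did not overlap for 1130 genes (11.0%), where chance gives 10% for 3 against 3. Of these, 706 were higher and 424 lower with rhCCL20. In data simulated on the same 10263 genes, 200 were changed at once. There the same test recovered 67.1% of genes changed by 0.322 on the log2 scale, 92.8% of genes changed 1.5-fold and 98.9% of genes changed 2-fold. With few changed genes the adjusted threshold is harder to reach. These shares therefore do not carry over to this comparison, where 1 gene passed. The genes next in rank were IFI27L2 at -0.33, HAGHL at -0.31, ECM1 at -0.34 and C1D at 0.35, each with a limma adjusted p of 0.704. Beside GAGE12G, 1 gene reached a log2 fold change of 1 in size, the readthrough transcript TNFAIP8L2-SCNM1, at 1.00 with a limma adjusted p of 0.937, named here after its value was seen.

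The transcripts of the chemokine and its receptor were scarce. CCR6 averaged 0.073 ± 0.049 FPKM in vehicle and 0.059 ± 0.054 FPKM with rhCCL20 (SD, n = 3 each), below the filter, and was not tested. The CCL20 transcript averaged 1.62 ± 0.74 FPKM in vehicle and 0.69 ± 0.53 FPKM with rhCCL20 (SD, n = 3 each), with overlapping groups. Its log2 fold change was -0.64 (95% interval -1.17 to -0.10, limma adjusted p = 0.937 over all genes and 0.0239 adjusted over the list alone, where it was the 1 tested member). In vehicle, CCL20 and the cytokine transcripts CXCL8 and IL1B were each lowest in replicate 2, and with rhCCL20 each was highest in replicate 2, while the cytokine LIF did not follow this order. CCL20 was at 1.88, 0.78 and 2.20 FPKM in vehicle replicates 1 to 3 and at 0.32, 1.30 and 0.45 FPKM in rhCCL20 replicates 1 to 3. CXCL8, which encodes interleukin 8, was at 7.77, 0.73 and 6.56 FPKM and at 1.95, 7.12 and 1.46 FPKM in the same libraries, and IL1B, which encodes interleukin 1 beta, at 9.67, 0.96 and 6.53 FPKM and at 1.6, 6.90 and 1.34 FPKM.

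**Figure D2:**
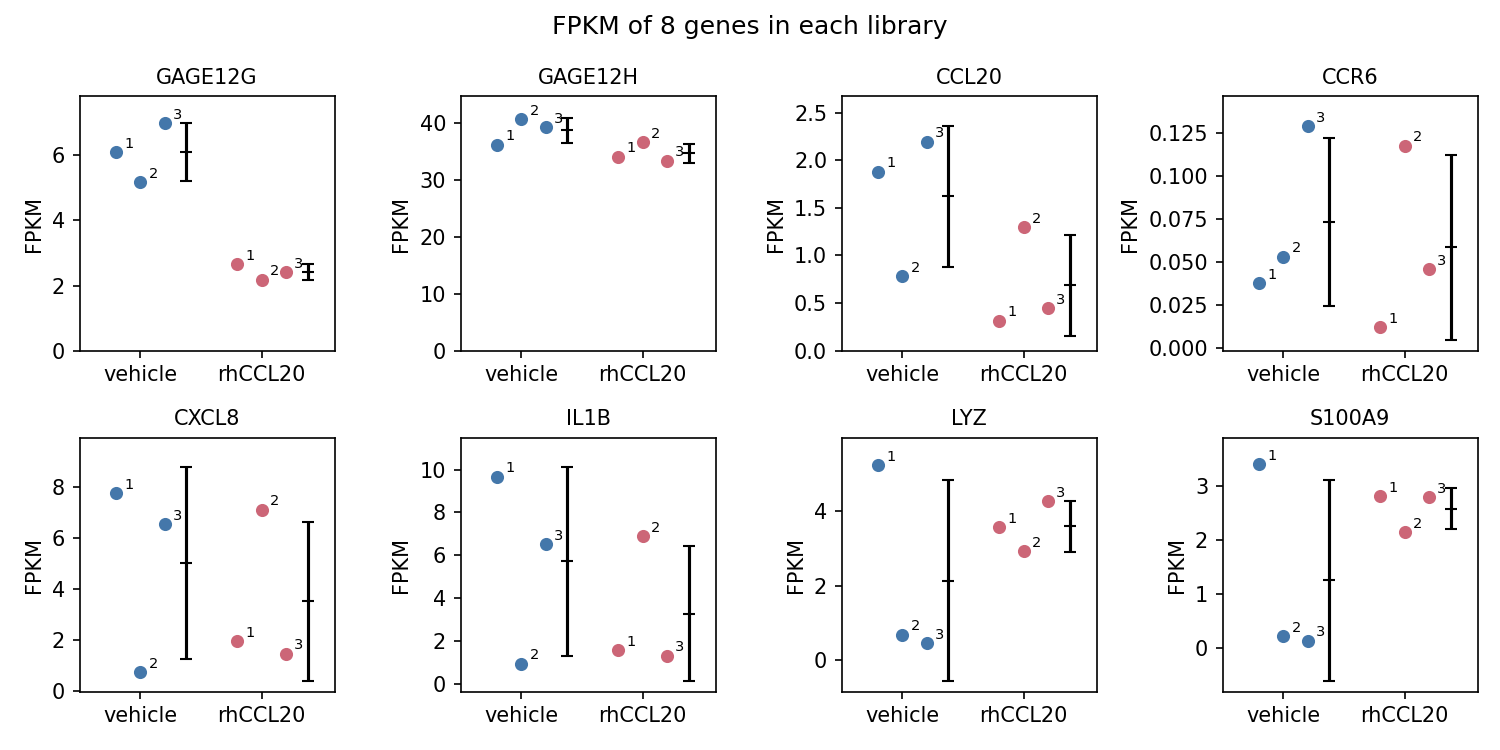
FPKM of 8 genes in each library, with replicate numbers beside the points and the mean and SD of each group (n = 3) as a bar. GAGE12G lies between 5.19 and 6.98 FPKM in vehicle and between 2.18 and 2.66 FPKM with rhCCL20, while CXCL8 and IL1B differ several fold between libraries in both groups, and LYZ and S100A9 in vehicle.

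Inflammatory and immediate early genes did not pass. In 19 tested NF-kB targets and inflammatory cytokines, 0 rose and 0 fell, and the median log2 fold change was -0.03. NFKBIA and ICAM1 serve as examples of abundant members with steady values. NFKBIA, the NF-kB inhibitor, was at 39.3 ± 2.1 and 37.7 ± 2.2 FPKM in vehicle and rhCCL20 (SD, n = 3 each). The adhesion receptor ICAM1 was at 35.4 ± 0.93 and 35.1 ± 0.98 FPKM (SD, n = 3 each). LIF, the member with the smallest p, had a log2 fold change of -0.14. Of the 19, 13 were lower and 6 higher, and the interval lay within 1.5-fold for 14. It was wide for IL1B at -0.57 (-1.92 to 0.78), the cytokine TNF at -0.57 (-1.51 to 0.38) and CXCL8 at -0.32 (-1.65 to 1.01). Changes of 2-fold in FPKM + 1 were therefore not excluded for these genes. Of 4 tested members of the other chemokines and receptors, 0 passed, with a median of -0.21 although camera gave the direction up, and CXCR4, the receptor for CXCL12, had a log2 fold change of 0.13. That median rests on single libraries, at 0.14 without vehicle replicate 1 or rhCCL20 replicate 2, where 2 members were tested, and at -0.60 without vehicle replicate 2. Of the 4 members 2 were higher and 2 lower, and the interval lay within 1.5-fold for 2. It was wide for the chemokine CCL4, at -0.83 (-2.10 to 0.43). The 17 immediate early genes and ERK feedback genes had a median of 0.06, with 0 past the threshold and IER2 at 0.08. The 17 interferon-stimulated genes had a median of -0.02 and 0 past the threshold, with the ubiquitin-like modifier ISG15 at -0.28. In each of these 4 lists 0 genes passed adjusted over the list alone.

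Adhesion, invasion and lineage genes did not pass either. The 11 epithelial junction and keratin genes had a median log2 fold change of -0.07, with the mucin MUC1 at 0.25, and the 16 mesenchymal genes had a median of 0.00 where camera gave the direction down, with ZEB2 at 0.10. The 14 matrix proteases, inhibitors and collagens had a median of 0.01, with LAMB3 at -0.16. Medians were 0.05 for 9 stem cell-associated genes (BMI1 at 0.12), 0.01 for 9 Notch pathway genes (NOTCH1 at 0.10), 0.03 for 8 Wnt genes (WNT5A at 0.07), 0.04 for 18 TGF-beta and YAP targets (SKIL at 0.11), 0.02 for 14 drug transporter and detoxification genes (CYP1B1 at 0.13) and 0.02 for 5 ovarian carcinoma lineage genes, where camera gave the direction down. For the last list and for 3 endothelial and mesothelial markers, which had a median of -0.10, the member with the smallest p was the mesothelial antigen MSLN at -0.10. In each of these lists 0 genes passed over all genes and 0 adjusted over the list alone.

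Among proliferation, stress and metabolism genes 0 passed over all genes. The 30 cell cycle genes had a median log2 fold change of 0.00, with TOP2A at 0.10. The 17 p53 targets and apoptosis regulators had a median of 0.03 (RRM2B at 0.11), the 14 heat shock genes 0.04 (HSPA1A at 0.15), the 17 NRF2 and oxidative stress genes 0.02 (AKR1B10 at 0.18), the 26 cholesterol and fatty acid synthesis genes 0.02 (SC5D at 0.15) and the 23 lysosome and autophagy genes 0.03 (CTSA at 0.09). The 23 hypoxia and glycolysis genes (PGAM1 at 0.10) and the 20 unfolded protein and integrated stress response genes (SDF2L1 at -0.12) each had a median of 0.01, where camera gave the direction down. The 28 nuclear-encoded respiratory chain genes had a median of -0.03 (COX5A at 0.10). Of 12 replication-dependent histone genes, with a median of 0.03, HIST2H2AC was the 1 that passed adjusted over the list alone. It was at 0.72 ± 0.18 and 1.48 ± 0.31 FPKM (SD, n = 3 each), a log2 fold change of 0.53 with a limma adjusted p of 0.704 over all genes. It reached 1 FPKM only in the rhCCL20 libraries and so met the filter through the group where it was higher, which favours such a call.

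Across 27 lists tested with camera at a preset correlation of 0.01, only the cytosolic ribosomal proteins passed, in the direction down. The median log2 fold change of its 43 members was -0.03, 30 members were lower and 13 higher, 0 passed singly, and RPS2 was at -0.08. The list had a Benjamini-Hochberg adjusted p of 0.00675 in camera (limma) at the preset correlation. The correlation estimated for this list was 0.753, far above the preset 0.01. With an estimated correlation the adjusted p in camera was 0.767. Without rhCCL20 replicate 3 its median was 0.01 and its direction up, with an adjusted p of 0.265 in camera. Without vehicle replicate 2 the adjusted p in camera was 0.524. The library of rhCCL20 replicate 3 stood apart from the rest, at 11.7 on the first principal component, which held 38.8% of the variance, where the others lay between -3.96 and -0.74. At the preset correlation, 6 of the 27 lists had an unadjusted camera p under 0.05. With an estimated correlation or with fry, 0 of the 27 lists passed. Under other settings 6 further lists passed in camera. The heat shock genes passed in the direction up with no filter, with quantile normalization, with a length and GC trend removed, without vehicle replicate 2 and without rhCCL20 replicate 3. The respiratory chain genes passed in the direction down without vehicle replicate 1 and without rhCCL20 replicate 1 or 2. In the direction up, the stem cell-associated genes passed with no filter and without vehicle replicate 1, and the leukocyte markers without vehicle replicate 1. In the direction down, the NF-kB targets and the endothelial and mesothelial markers passed without vehicle replicate 2. With an estimated correlation 0 lists passed in any setting, and the smallest adjusted p in camera was 0.561. With fry, 1 list passed in 1 setting, the NRF2 and oxidative stress genes without rhCCL20 replicate 1.

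**Figure D3:**
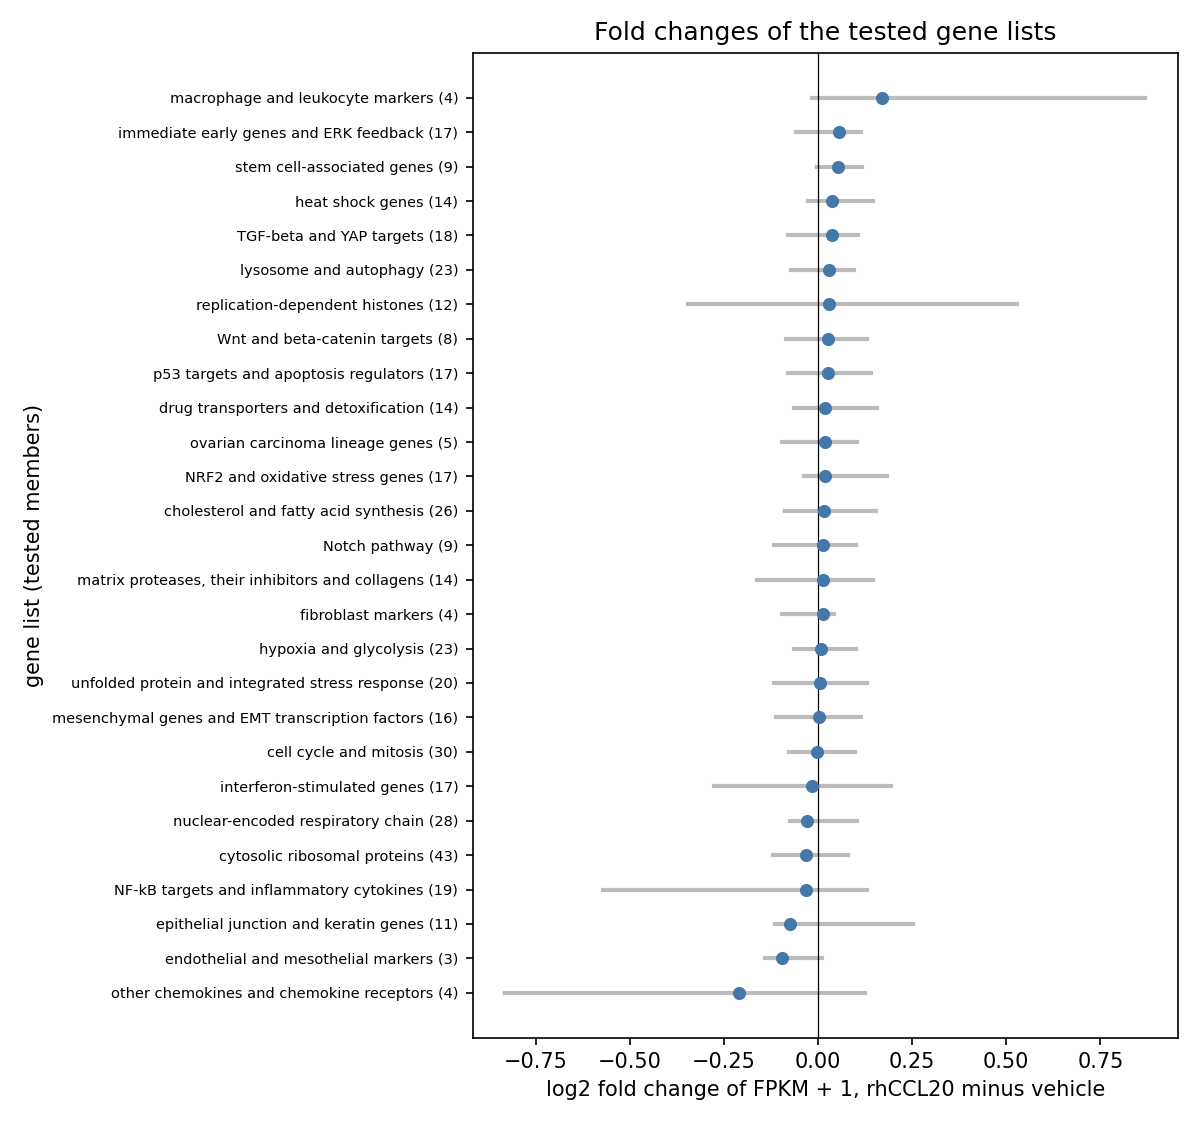
Median log2 fold change of FPKM + 1 (rhCCL20 minus vehicle, points) and range over tested members (bars) for the 27 tested gene lists, with the number of tested members in parentheses. The medians lie between -0.21 for the other chemokines and receptors and 0.17 for the macrophage and leukocyte markers, and both of these depend on which libraries are kept.

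Markers of leukocytes and fibroblasts did not pass. Of 4 tested macrophage and leukocyte markers 0 passed, with a median log2 fold change of 0.17. It was 0.03 without rhCCL20 replicate 1 or 3, where 3 members were tested, and 0.35 with a pseudocount of 0.1. Of 4 tested fibroblast markers 0 passed, with a median of 0.01, while their mean was -0.01 and camera gave the direction down, with PDGFRB at -0.10. LYZ, which encodes the lysozyme of myeloid cells, was at 5.24, 0.69 and 0.47 FPKM in vehicle replicates 1 to 3 and at 3.58, 2.92 and 4.27 FPKM in rhCCL20 replicates 1 to 3. Its log2 fold change was 0.87 (95% interval -0.11 to 1.85, limma adjusted p = 0.937). Without vehicle replicate 1 it was 1.53, with a limma adjusted p of 0.00317.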

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

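The summed GAGE genes and the removal of a length and GC trend were chosen after the data were seen. The planned tests for counts (DESeq2, voom and other count scalings and filters) were not run because the files hold FPKM. The count of 1 gene past the threshold in limma, GAGE12G, and of 1 with a fold of at least 2, was 0 for both with no filter on low values, where 861 had an unadjusted p under 0.05 and the unadjusted p of GAGE12G was 5.6e-05 against 6.94e-07 at the same fold, and 0 for both with the GAGE genes summed. Leaving out each library gave 1 to 3 genes, and 0 to 3 with a fold of at least 2. The 3 came without vehicle replicate 1, and the 0 without vehicle replicate 3 and without rhCCL20 replicate 2, where the log2 fold change of GAGE12G was -0.96 and -0.999. Lists past the threshold numbered 1 with camera, 3 with no filter, 0 with an estimated correlation, 0 with fry, 0 with fry in either direction, and 1 to 4 when each library was left out. They numbered 4 without vehicle replicate 1, 3 without vehicle replicate 2, and 2 without rhCCL20 replicate 1 or 2. The cytosolic ribosomal list turned to the direction up without rhCCL20 replicate 3 (median log2 fold change 0.0104, camera adjusted p = 0.265). Over the left-out libraries its median lay between -0.051 and 0.0104 and its adjusted p between 1.34e-06 and 0.524. It stayed down but lost its call with quantile normalization (adjusted p = 0.439, median -0.0038 against -0.0309), without vehicle replicate 2 (0.524, -0.0044) and with the trend removed (0.341, -0.0173). With quantile normalization, with the trend removed and without rhCCL20 replicate 3, the 1 list past the threshold was the heat shock genes, in the direction up, with an adjusted p of at least 0.561 at an estimated correlation. The median of the other chemokines and receptors (-0.21) was 0.118 with the filter at 5 FPKM, 0.140 without vehicle replicate 1, 0.138 without rhCCL20 replicate 2 and -0.598 without vehicle replicate 2. That of the leukocyte markers (0.17) was 0.354 and 0.401 with smaller pseudocounts. It was 0.03 with no filter (15 members tested) and without rhCCL20 replicate 1 or 3 (3 members tested). The median of the endothelial and mesothelial markers (-0.10) was -0.002 with no filter (9 members tested). Beyond the construction of the sum and the removal of the length and GC trend, causes of these shifts were not tested. The replicate number as a block left 1 gene, GAGE12G, and 1 list past the threshold. Same-numbered libraries correlated at -0.10, 0.03 and 0.10 in their deviations. Differently numbered libraries reached -0.12 and 0.13. These values show no pairing by number, but with 3 libraries per group they cannot exclude one. For the named genes, 521 alternative fold changes kept direction and side of the threshold, 1 lost the call (GAGE12G with no filter) and 1 gained it (LYZ without vehicle replicate 1). Unknown depth limits the reading of genes near 1 FPKM.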

Other observations

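The tests of the summed GAGE genes, of the other GAGE copies, of NF-kB targets, of the trend on length and GC content, and of the activated myeloid list without near-identical copies were chosen after the results were seen. Whether the varying transcripts go with LYZ or IL1B, and whether a list holds a gene of the split itself, was also asked afterwards, and the labels of the leukocyte lists were set again by it. The lists of leukocyte transcripts and the test of the ERBB2 neighbours were written before those values were seen.

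Some further genes were at high levels in both groups. The protease inhibitor A2M averaged 163 FPKM over the 6 libraries, and the log2 fold change was 0.01 (95% interval -0.08 to 0.11). The surface glycoprotein CD83 averaged 158 FPKM with a log2 fold change of 0.00 (95% interval -0.08 to 0.08). Of the cancer/testis antigens of the MAGEA family, MAGEA1 averaged 33.7 ± 0.23 FPKM in vehicle and 35.6 ± 0.24 FPKM with rhCCL20 (SD, n = 3 each), a log2 fold change of 0.08 (95% interval 0.00 to 0.15) that did not pass in limma (adjusted p = 0.937). MAGEA6 averaged 27 FPKM over the 6 libraries, while MAGEA4 was listed at 0 in all 6 libraries. These genes were chosen after their values were seen.

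ERBB2 and CDKN2A are at levels that go against what is known of SKOV3, a line with amplified ERBB2 and deleted CDKN2A. If the amplification were present, its neighbours on 17q12 should be abundant too. GRB7, STARD3, PGAP3 and MIEN1 averaged 3.87, 6.89, 1.58 and 24.4 FPKM, and their median percentile among the tested genes was 34.8, far below the 90 set beforehand for an amplified region. The values are consistent with cells of another line, or with cells without that amplification, as a hypothesis, and a deleted CDKN2A would not give 15.3 FPKM or more in each library. Expression cannot name the line, and genotypes were not analysed here.

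The lower GAGE12G may come from how reads are divided among near-identical copies, from chance, or from exposure to rhCCL20. The sum of the 12 listed copies had a log2 fold change of -0.24 (95% interval -0.35 to -0.14). It cannot decide on a mere shift among them, since it holds GAGE12G itself. FPKM is also scaled by transcript length, so reads moved between copies of unlike length need not keep the sum. The sum of the other 11 copies was lower, at -0.14 (95% interval -0.26 to -0.03), where reads moved to them from GAGE12G would raise it. That sum was mostly GAGE12H, and not every copy was lower. GAGE12B averaged 1.52 ± 1.98 FPKM in vehicle and 2.24 ± 1.77 FPKM with rhCCL20 (SD, n = 3 each). With copies of like length, a rise of 0.11 in the sum of the other 11 would take up the loss. Reads lost to copies outside the list, or dropped for matching several copies, stay open, and so does an effect of the exposure. Of the 10 splits of the 6 libraries 2 gave at least as many genes, the real one with 1 and another with 8, and 10 splits are too few to give a share under 0.05.

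The split with 8 genes set vehicle replicates 1 and 3 and rhCCL20 replicate 2 against the rest and called CCL3, CCL3L3, CCL4, CXCL8, IL1A, IL1B, TNF and HIST1H2BL, which points to a structure of the samples other than treatment, while LYZ and S100A9 followed a different order of libraries. On NF-kB activity of the whole culture, 63.2% of all tested members of that list (12 of 19) had a 95% interval within 1.5-fold in that split. Among them were all 8 with at least 5 FPKM. Another 5 members had a fold change of at least 1.5-fold (CXCL2, CXCL8, IL1A, IL1B and TNF). Of these, CXCL8, IL1A, IL1B and TNF are among the genes called in that split, which was picked for having most calls. CCL2 at -0.32 (95% interval -0.65 to 0.0009) and CCL5 at -0.33 (-0.75 to 0.09) fell in neither class and were lower in the rest, like those 5. Of members left out by the filter, CXCL1, CXCL3 and PTGS2 followed the split, IL6 and TRAF1 did not, and CSF2 was at 0. The share speaks against such activity only where it would move the 8 members with at least 5 FPKM. Low members are left open, since log2(FPKM + 1) shrinks their changes. Traces of activated myeloid cells stay open as a source. Of a list of their transcripts, 20% (3 of 15) varied more than 95% of genes of like level. That share lies exactly at the bound set for a trace. The varying transcripts were low, with G0S2 at 0.31, IL1RN at 0.299 and SERPINB2 at 0.584 FPKM over the 6 libraries. G0S2 and SERPINB2 were higher in vehicle replicates 1 and 3 and rhCCL20 replicate 2 than in the rest. IL1RN was highest in rhCCL20 replicate 1 (0.52 FPKM) and did not follow that split. The share meets the bound only with IL1RN counted. With CCL3L3, itself called in that split, and CCL4L2 counted, the share was 29.4% (5 of 17), which decides nothing. Traces of resting blood myeloid cells may account for LYZ and S100A9, with 33.3% of their other transcripts (6 of 18) varying as much and going with LYZ over the libraries, at averages such as 1.54 FPKM for HLA-DRA and 0.93 for CD74, although CSTA, at 2.89 FPKM, varied less than most genes of like level (percentile 13.8). Traces of whole blood stay open, since of lymphocyte, plasma cell and erythroid transcripts 33.3% (6 of 18) varied as much but only 2 of these 6 went with LYZ in at least 3 libraries, HBA1 being highest in vehicle replicates 2 and 3 (1.54 and 1.26 FPKM), where LYZ was lowest, and HBB and MZB1 above 0 only in vehicle replicate 1.

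The deviation of rhCCL20 replicate 3 from the other libraries had a Spearman rho across genes of 0.475 with transcript length and -0.04 with GC content, genes not being independent replicates. The rho with length was -0.39 in vehicle replicate 2 and -0.28 in rhCCL20 replicate 2, and that with GC content -0.28 in rhCCL20 replicate 2 and 0.22 in vehicle replicate 3. With a trend on both removed, rhCCL20 replicate 3 stood at 10 on the first principal component, the others lying between -2.87 and -0.02.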
